A study of Arabidopsis thaliana with 6 samples.

How the data were processed

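The series holds 6 whole-plant samples of Arabidopsis thaliana Col-0, 3 labelled as control and 3 as CsCl-treated by their treatment label. Total RNA was taken with a column kit and treated with DNase, and libraries were made with a stranded mRNA kit, per the labels' protocols. The deposited files give raw counts per gene, 1 file per sample, with no normalization. The submitters' processing notes name FastQC, STAR, featureCounts and edgeR and the TAIR10 build without versions, and the annotation release, strand setting and treatment of multi-mapped reads are not given in the sources used here. Each file lists the same 33977 IDs: 32548 locus IDs of the 5 chromosomes, 133 chloroplast, 152 mitochondrial and 1144 ENSRNA IDs. Nothing says whether the 3 samples of a group came from separate plates or sowings, so p-values measure only the spread between these samples, which may be technical.

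The counts show 2 features of how they were made. Of values from 1 to 50, between 65.5% and 73.4% were even in each library, and 814 genes had a count of 2 against 525 with a count of 1 in control replicate 1, so both mates of a pair appear to have been counted. Low counts then rest on about as many fragments as the count divided by 2. The copies of 1 chloroplast ribosomal RNA gene had nearly equal counts (205754 and 205698 in control replicate 1), so multi-mapped reads appear to have been counted at each copy, and near-identical genes cannot be told apart. Since the strand setting is unknown, overlapping antisense genes are open to the same doubt.

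Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the group (21005 genes kept), TMM factors (0.961 to 1.03), quasi-likelihood fit and test with default settings, Benjamini-Hochberg adjustment and a threshold of 0.05. The model had the group as its only term. Log2 fold changes are CsCl over control; their SE is the size of the unshrunk coefficient divided by the square root of F. The common dispersion was 0.00636. CPM are relative to the TMM-scaled library sizes. All named values of CPM are mean ± SD over 3 libraries. Total counts ran from 32075069 to 44108369 per library. Counts were simulated for this comparison, each gene on its own at the dispersion trend of the data, with 20867 genes tested. The fit recovered 51 of 67 genes changed 1.5-fold, 62 of 67 changed 2-fold and 63 of 66 changed 4-fold. Its 190 calls also held 7 unchanged genes and members of a set of 20 genes shifted by 0.4 on the log2 scale. Correlated genes, a spread particular to a gene and doubled mates were not simulated, so the fit may do worse on the real counts.

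For 26 gene lists with 547 members, fixed before the data were examined, members higher, lower and not past the test were counted, adjusted over all genes and over the list alone. Set tests used limma 3.58.1 on log2 CPM with a prior count of 2: camera with a correlation preset at 0.01, camera with an estimated correlation, and fry, each adjusted over the 26 lists. Camera compares a list with other genes; fry asks whether a list's genes move one way on balance. All 9 lists called by camera with the preset correlation (3 higher, 6 lower) lost the call with an estimated correlation; fry called 2 higher and 2 lower. List members were matched to the TAIR10.1 gene table: 515 by symbol, 31 by locus only, and 1, CNX2, was moved by the rule for symbols to AT2G31955, a molybdenum cofactor gene, although AT5G07340 was meant. TAIR10.1 was used for names, GC content and length, and no coordinates are given. All 32548 chromosomal IDs matched it, and organelle and ENSRNA IDs are printed as deposited.

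Named genes followed a rule fixed at the same time: the 8 largest rises and 8 largest falls past the test with a mean CPM of at least 5 and no overlap between groups; in each list the 2 members with the smallest adjusted p per direction (4 for small heat shock proteins, large heat shock proteins and ER stress); HSP101, HSFA2, HSP90.1, BIP3, BZIP60, HAK5 and AKT1 in any case; and the 5 most abundant genes. Samples of a group differed by more than sampling noise in every pair (chi-square per gene of 6.39 to 13.1), so no 2 libraries were copies of each other. Shared stretches between transcripts were searched with BLAST 2.17.0, as windows of 100 aligned bases at 95% identity or more.

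Alternatives fixed beforehand were RLE, upper-quartile and no scaling factors, no filter and a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, robust edgeR, the replicate number as a block, leaving out each library, leaving out organelle genes, an adjusted p under 0.01 and a test against a fold of 2. Thinned libraries, halved counts, a smooth correction for GC content and transcript length (mgcv 1.9.3) and CNX2 at its meant locus were added after seeing the data. Term enrichment used the annotation notes of TAIR10.1, with terms of 10 to 500 genes and a one-sided hypergeometric (Fisher's exact) test against the 13666 tested genes that carry such notes.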

Results

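Messenger RNA was sequenced from whole Arabidopsis thaliana plants of the Col-0 accession after 10 days at 22 °C under 16 h of light and 8 h of dark. The 3 control samples grew on half-strength MS medium, a standard mineral plant medium, and the 3 treated samples grew on the same medium with 1.5 mM cesium chloride (CsCl). Cesium is an alkali metal ion chemically close to potassium. The control libraries held 32694267, 33416318 and 35442349 counts and the CsCl libraries 32075069, 34803640 and 44108369, so CsCl replicate 3 was the deepest. The comparison asks which transcripts differ between plants grown with and without CsCl, and the series title directs attention to heat shock proteins and the endoplasmic reticulum (ER) stress response.

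With CsCl, 7 of 16 tested small heat shock protein genes were higher, and 9 of 13 genes of glucosinolate synthesis and 12 of 21 of sulfate uptake and assimilation were lower. As whole lists these 3 were past a set test with a preset correlation, but not with an estimated correlation (adjusted p = 0.135, 0.299 and 0.299). Among moderately abundant genes, the lipid-transfer-type protein gene EARLI1 (AT4G12480) went from 0.789 ± 0.303 to 15.0 ± 1.77 CPM (counts scaled to a common library size; mean ± SD, n = 3 per group). The chloroplast superoxide dismutase gene CSD2 (AT2G28190) rose 2.4-fold, from 25.6 ± 1.61 to 61.5 ± 2.58 CPM. The cytochrome P450 gene CYP79F1 (AT1G16410), which acts in methionine-derived glucosinolate synthesis, fell from 139 ± 10.8 to 69.2 ± 8.84 CPM, and the sulfur-deficiency marker SDI1 (AT5G48850) from 25.5 ± 4.30 to 11.2 ± 2.19 CPM. Transcripts of photosynthesis, potassium transport and the heat shock transcription factors had no member past the test.

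Of 21005 genes tested, 177 were higher and 277 lower with CsCl (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The rises were larger than the falls: 81 genes were at least 2-fold higher and 13 at least 2-fold lower, with median log2 fold changes of 0.91 among the higher and -0.43 among the lower genes. In 453 of the 454 genes past the test, all 3 CsCl libraries lay on one side of all 3 control libraries. Among all tested genes 19.8% showed such a separation, against 10% by chance. The first principal component of log2 CPM held 35.7% of the variance and separated the groups. Without CsCl replicate 2 the counts were 92 higher and 90 lower, without CsCl replicate 3 they were 89 and 133, and without control replicate 2 the higher count was 113; scaled by total counts alone, 198 were higher and 180 lower, so that 52.4% of the calls were higher in place of 39.0%. The count at least 2-fold higher was 53 without CsCl replicate 3, the count at least 2-fold lower was 7 without CsCl replicate 2, and a test against a fold of 2 itself called 20 higher and 1 lower, the ferric reductase gene FRO5 (AT5G23990), which was chosen after its values were seen.

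Small heat shock proteins, chaperones that bind unfolding proteins, had 7 of 16 tested members higher and none lower, or 9 higher when adjusted over the list alone. The cytosolic AT1G53540 rose from 0.540 ± 0.0663 to 4.95 ± 0.434 CPM, a log2 fold change of 3.19 ± 0.21 (SE; edgeR adjusted p = 1.90e-06). HSP17.6A (AT5G12030) rose from 0.420 ± 0.0647 to 4.16 ± 0.968 CPM and HSP17.6II (AT5G12020) from 0.380 ± 0.0365 to 3.02 ± 0.119 CPM. The mitochondrial HSP23.6-MITO (AT4G25200) had 2, 2 and 4 counts in the control libraries and 47, 40 and 76 with CsCl, a ratio of 18 with a 95% interval of 8.98 to 42.7 from the summed counts. That interval covers counting error only and takes each count as independent, so it is too narrow if both mates of a pair were counted. The related AT5G51440, at a higher level, rose 2.36-fold from 5.37 ± 1.31 to 12.7 ± 0.572 CPM. The list was past the set test with a preset correlation (camera adjusted p = 4.49e-12) and by fry (adjusted p = 0.0011), and not with an estimated correlation (adjusted p = 0.135). This list and those of large heat shock proteins, heat shock factors and ER stress were fixed knowing the series title, so their direction is not independent evidence.

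Large heat shock proteins and co-chaperones had 4 of 25 tested members higher and none lower, all less than 2-fold. Adjusted over the list alone, 6 were higher and 1 lower. The HSP70 family gene HSC70-2 (AT5G02490) rose from 19.4 ± 1.35 to 30.2 ± 2.42 CPM (log2 fold change 0.64 ± 0.082, edgeR adjusted p = 0.000878), while HSP70B (AT1G16030) rose 1.58-fold, FES1A (AT3G09350) 1.41-fold and HSP90.1 (AT5G52640) 1.46-fold. The disaggregase gene HSP101 (AT1G74310) stood at 21.8 ± 2.52 CPM in controls and 22.2 ± 0.783 with CsCl (edgeR adjusted p = 0.924), and its fold change near 0 turned sign without control replicate 1. The list's camera adjusted p was 0.0123 with the preset correlation, 0.660 with an estimated correlation and 0.20 by fry. With control replicate 2 or any 1 of the CsCl replicates left out, 2 members were higher. HSP70B lost its call without control replicate 2 or CsCl replicate 3, FES1A without control replicate 3 or CsCl replicates 1 or 2, and HSP90.1 in 4 of the 6 fits that left out a library and with robust estimation.

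**Figure D1:**
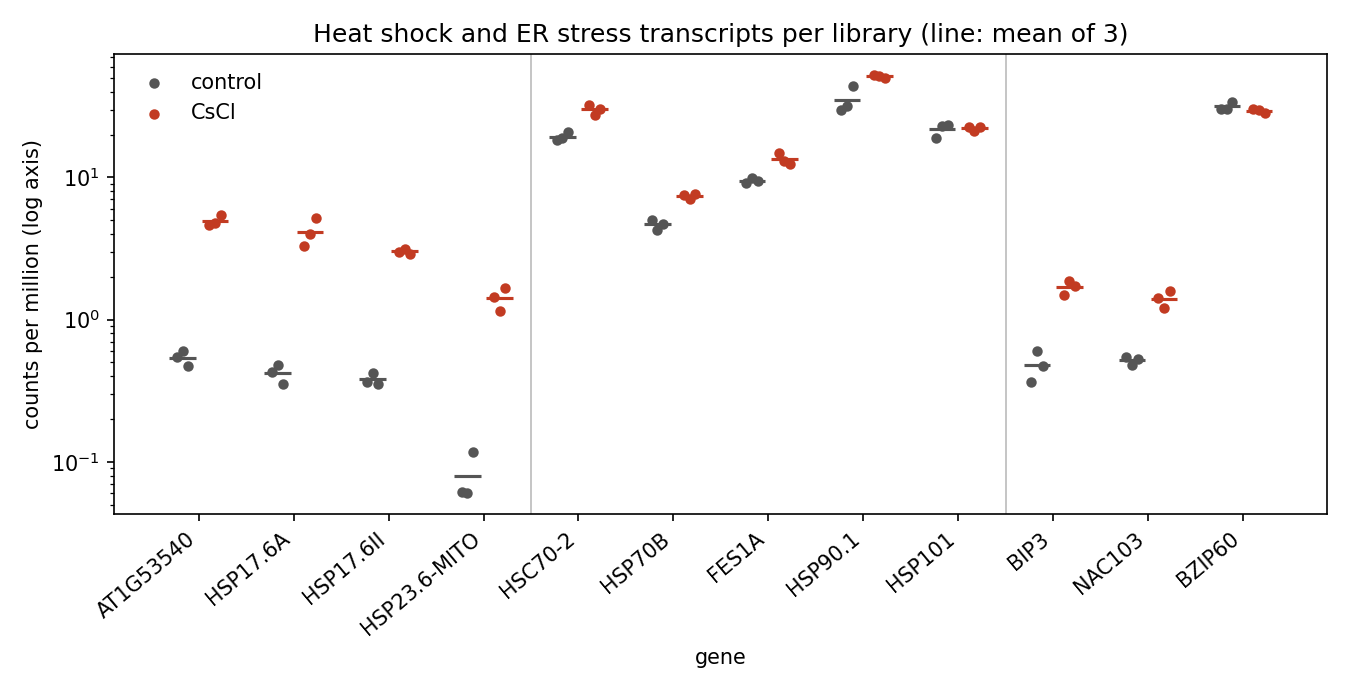
CPM on a log axis for 12 genes, one point per library with the group mean as a line (grey, 3 control libraries; red, 3 CsCl libraries); vertical lines part small heat shock proteins, large heat shock proteins with co-chaperones, and ER stress genes. The small heat shock protein genes are separated most, with AT1G53540 at a mean of 0.540 in controls and 4.95 with CsCl, while the groups overlap for HSP101.

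No heat shock transcription factor passed the edgeR test among 18 tested, and 2 did at an unadjusted p under 0.05, against 0 with DESeq2 and 0 with limma-voom. HSFA2 (AT2G26150), a heat-induced member, stood at 1.55 ± 0.286 CPM in controls and 2.71 ± 0.231 with CsCl (log2 fold change 0.79 ± 0.22, edgeR adjusted p = 0.0814), and passed with no filter on low counts (adjusted p = 0.0453; 0.226 at most over the alternatives). ER stress and ER protein folding had 2 of 38 tested members higher and none lower, and likewise 2 when adjusted over the list alone. These were BIP3 (AT1G09080), an ER chaperone gene induced when proteins misfold there, at 0.479 ± 0.118 and 1.69 ± 0.192 CPM, and the transcription factor gene NAC103 (AT5G64060), at 0.519 ± 0.0344 and 1.4 ± 0.194 CPM. The list as a whole was not past camera (adjusted p = 0.687) or fry (adjusted p = 0.298), and its median log2 fold change was 0.0032. BZIP60 (AT1G42990), a transcription factor gene of the same response, stood at 31.7 ± 2.1 and 29.5 ± 0.911 CPM (edgeR adjusted p = 0.546). Counts per gene give its total level only and cannot show a change in splicing. NAC103 lost its call with the replicate number as a block and in 5 of the 6 fits that left out a library (every one except that without control replicate 1), which left 1 member higher.

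Glucosinolate synthesis, the pathway of sulfur-rich defence compounds, had 9 of 13 tested members lower and none higher, or 10 lower when adjusted over the list alone. MAM1 (AT5G23010), which elongates the methionine chain, fell from 198 ± 3.49 to 112 ± 10.4 CPM (log2 fold change -0.83 ± 0.068, edgeR adjusted p = 1.79e-05), and CYP79F1 fell by 1.00 ± 0.086 on the log2 scale (edgeR adjusted p = 2.33e-05). The list's median log2 fold change was -0.42. It was past camera (adjusted p = 7.13e-10) and fry (adjusted p = 0.0291), but not with an estimated correlation (adjusted p = 0.299).

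Sulfate uptake and assimilation had 12 of 21 tested members lower and none higher, or 16 lower when adjusted over the list alone. SDI1 showed a log2 fold change of -1.19 ± 0.14 (edgeR adjusted p = 0.000396), and the sulfate transporter gene SULTR2;1 (AT5G10180) fell from 151 ± 6.78 to 113 ± 6.29 CPM. LSU3 (AT3G49570), a low-sulfur marker outside the list, fell from 11 ± 1.35 to 5.14 ± 1.42 CPM. The list's camera adjusted p was 1.43e-11 with the preset correlation, 0.299 with an estimated correlation and 0.0545 by fry. The count of lower members was 4 without CsCl replicate 2, 5 without CsCl replicate 1 and 7 without control replicate 3.

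**Figure D2:**
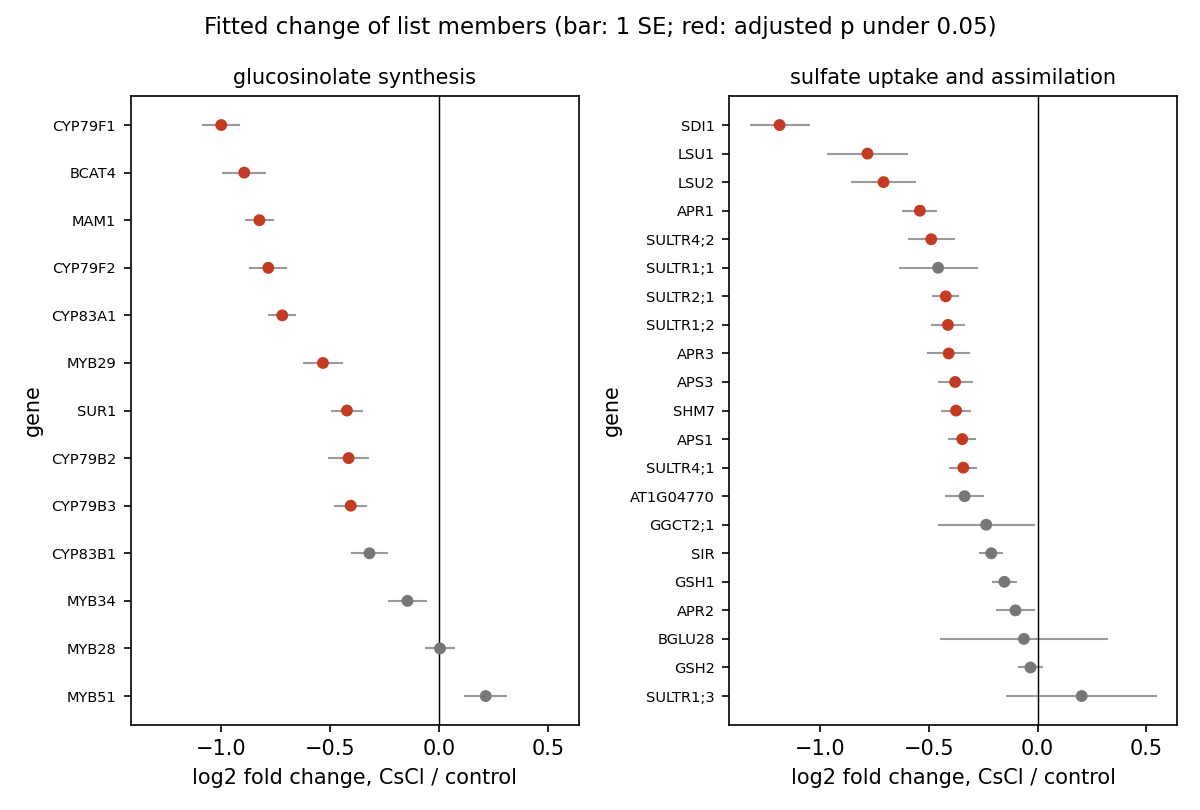
Fitted log2 fold change of CsCl over control for every tested member of 2 gene lists, with bars of 1 SE from the edgeR fit and red points at adjusted p under 0.05. Red points number 9 of 13 for glucosinolate synthesis and 12 of 21 for sulfate uptake and assimilation, all to the left of 0.

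Markers of root tissue moved in the same direction as these 2 lists. Of 15 tested root tissue markers, 4 were lower and none higher, or 5 lower when adjusted over the list alone, with a median log2 fold change of -0.23. The count of lower members was 1 without CsCl replicate 2, and 2 without control replicate 3 or CsCl replicate 3. The endodermal CASP2 (AT3G11550), a Casparian strip protein gene, fell from 25.8 ± 1.74 to 18.7 ± 0.802 CPM. PYK10 (AT3G09260), a root-abundant beta-glucosidase gene, fell from 5788 ± 171 to 4462 ± 299 CPM, a call lost without CsCl replicate 2 and with the replicate number as a block. Of 13 root hair markers 2 were lower and none higher, or 5 when adjusted over the list alone: the cell wall protein genes PRP1 (AT1G54970) fell by 0.34 ± 0.075 and PRP3 (AT3G62680) by 0.36 ± 0.080 on the log2 scale. PRP1 lost its call without either of control replicates 1 and 2 or CsCl replicates 2 and 3, and PRP3 without control replicate 3 or CsCl replicates 2 or 3; both lost it when scaled by total counts alone, and PRP3 after the GC and length correction. Camera adjusted p was 0.00209 for root tissue and 0.00103 for root hair markers, against 0.299 and 0.564 with an estimated correlation, and fry gave 0.0295 and 0.193. Among root hair markers 1 was lower with any 1 of the control libraries left out, and 0 without CsCl replicate 2 or 3 (edgeR; 5 at an unadjusted p under 0.05 with all libraries, and 2 each with DESeq2 and limma-voom).

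Antioxidant enzymes and oxidative stress markers had 4 of 21 tested members higher and none lower, also 4 when adjusted over the list alone. CSD2 had a log2 fold change of 1.26 ± 0.068 (edgeR adjusted p = 2.06e-07), and AT2G21640, a marker of oxidative stress, rose from 0.960 ± 0.120 to 7.07 ± 1.67 CPM. The other 2, named after their values were seen, were the cytosolic superoxide dismutase gene CSD1 (AT1G08830), at a log2 fold change of 1.22, and the alternative oxidase gene AOX1A (AT3G22370), at 0.40. Camera adjusted p was 0.0155 with the preset correlation and 0.299 with an estimated correlation, and fry gave 0.00982. Among 10 glutathione transferases 1 was higher, GSTF7 (AT1G02920), at 11.8 ± 1.36 and 18.9 ± 2.76 CPM, and the call was lost without CsCl replicate 3; 2 were higher when adjusted over the list alone, and 2 without control replicate 1. Abscisic acid, drought and cold genes had 5 of 25 members lower and none higher, or 8 lower when adjusted over the list alone. The dehydrin gene COR47 (AT1G20440) fell from 299 ± 5.72 to 225 ± 4.25 CPM and RD29A (AT5G52310) from 28.9 ± 3.99 to 18.6 ± 1.08 CPM. With control replicate 3 or CsCl replicate 2 or 3 left out 2 members were lower, and without control replicate 1 there were 3. RAB18 (AT5G66400), KIN1 (AT5G15960) and RD22 (AT5G25610), named after their values were seen, had log2 fold changes of -0.48, -0.81 and -0.30. The list's camera adjusted p was 7.92e-05 with the preset correlation, 0.564 with an estimated correlation and 0.20 by fry.

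Defence and hormone lists had few members past the test. Of 22 salicylate and pathogen defence genes 1 was higher, PR1 (AT2G14610), and 1 lower, EDS5 (AT4G39030), which fell from 17 ± 0.454 to 12.4 ± 1.08 CPM; the same numbers held when adjusted over the list alone. PR1 had 2, 4 and 6 counts in controls and 22, 11 and 194 with CsCl, and its call was lost without CsCl replicate 3 or any of the 3 control libraries, with limma-voom and with robust estimation. EDS5 lost its call without CsCl replicate 1 or 2. Without CsCl replicate 1, 2 members of this list were higher. The senescence and chlorophyll breakdown list had 1 of 12 higher, SAG13 (AT2G29350), with 3, 0 and 8 counts in controls and 58, 32 and 420 with CsCl, and the call was lost with limma-voom and with robust estimation. Jasmonate synthesis and response had 1 of 24 lower, VSP1 (AT5G24780), at 34.9 ± 5.85 and 22.7 ± 2.51 CPM, which was lost without CsCl replicate 2. Phosphate starvation had 1 of 13 lower, PHO1;H1 (AT1G68740), which fell by 0.36 ± 0.084 on the log2 scale and kept its call in 1 of the 6 fits that left out a library, and lost it with upper-quartile factors, total counts only and the replicate block. The senescence, jasmonate and phosphate lists gave the same numbers when adjusted over the list alone.

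Potassium transport had no member past the edgeR test among 37 tested, with 6 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom. The high-affinity potassium transporter gene HAK5 (AT4G13420) stood at 9.63 ± 1.58 CPM in controls and 6.72 ± 0.475 with CsCl (log2 fold change -0.52 ± 0.13, edgeR adjusted p = 0.0582). It passed with DESeq2 (adjusted p = 0.0202), with no filter on low counts (0.0139), with robust estimation (0.0416) and without control replicate 2 (0.0230), and the adjusted p over all alternatives reached 0.174. The potassium channel gene AKT1 (AT2G26650) stood at 48.3 ± 1.94 and 54.2 ± 4.89 CPM (edgeR adjusted p = 0.308). In the photosynthesis list, 0 of 41 passed, 8 did so at an unadjusted p under 0.05, 2 with DESeq2 and 1 with limma-voom. With 36 of 41 fold changes below 0, camera called that list lower (adjusted p = 0.000765; 0.720 with an estimated correlation), at a median log2 fold change of -0.073.

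In all, 12 of the 26 lists had no member past the edgeR test: besides the heat shock factors, potassium transport and photosynthesis, these were chlorophyll biosynthesis, ethylene, iron, nitrogen, flavonoid synthesis, auxin and cytokinin response, cell division, stomatal markers and the circadian clock. Of their 243 tested members, 38 had an unadjusted p under 0.05, 3 passed with DESeq2 and 1 with limma-voom. Among all 21005 tested genes, 3029 had an unadjusted edgeR p under 0.05, so these 38 do not by themselves set the lists apart. Without control replicate 1, 3 iron genes and 1 auxin and cytokinin response gene were higher and 1 photosynthesis gene was lower, and without control replicate 2, 1 potassium transport gene was lower. Adjusted over the list alone, 1 heat shock factor passed and no member of the other 11 lists did. Median, mean and test differed in sign for 3 lists that camera did not call. Glutathione transferases had a median of -0.059 and a mean of 0.014 with the test pointing up, flavonoid synthesis a median of 0.0079 and a mean of 0.065 with the test pointing down, and auxin and cytokinin response a median of 0.00046 and a mean of -0.060 with the test pointing down.

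The remaining genes named by the size of their rise were the defence-priming gene AZI1 (AT4G12470), from 5.28 ± 0.580 to 27.4 ± 6.61 CPM, the trypsin inhibitor gene TI1 (AT2G43510), from 2.55 ± 0.815 to 10.9 ± 4.55, the pectin lyase-like AT3G27400, from 4.07 ± 0.884 to 11.9 ± 2.47, the jasmonate-regulated JRG21 (AT3G55970), from 3.89 ± 0.189 to 10.4 ± 4.57, and the transcription factor gene WRKY60 (AT2G25000), from 3.51 ± 1.22 to 8.54 ± 1.18. Those named by the size of their fall were CYP716A2 (AT5G36140), from 8.18 ± 4.14 to 3.33 ± 0.317 CPM, PYD4 (AT3G08860), from 11.7 ± 2.60 to 4.79 ± 0.928, the basic helix-loop-helix gene AT1G71200, from 7.40 ± 0.561 to 3.56 ± 0.472, the isochorismate synthase gene ICS2 (AT1G18870), from 74.1 ± 19.5 to 36.0 ± 6.03, and the beta-glucosidase gene BGLU25 (AT3G03640), from 41.9 ± 1.06 to 20.7 ± 0.940. JRG21 lost its call without CsCl replicate 3, CYP716A2 without any 1 of the CsCl libraries and with DESeq2 and limma-voom, and TI1, JRG21, CYP716A2 and ICS2 with robust estimation. The 5 most abundant transcripts were RCA (AT2G39730), LHCB1.3 (AT1G29930), RBCS1A (AT1G67090), RBCS3B (AT5G38410) and the chloroplast ribosomal RNA ATCG00950. None was past the test, with log2 fold changes of -0.051, -0.21, -0.030, -0.16 and 0.33. RCA turned sign without control replicate 3 (0.033), and RBCS1A with total counts only (0.0080); RBCS3B passed with DESeq2 (adjusted p = 0.0486, and up to 0.520 over the alternatives) and ATCG00950 without CsCl replicate 1 (adjusted p = 0.0164, and up to 0.730).

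Chloroplast genes took 1.98, 1.64 and 1.95% of the counts in controls and 1.70, 2.64 and 2.77% with CsCl (two-sided exact permutation p = 0.3). These shares include both copies of a chloroplast ribosomal RNA gene, ATCG00950 and ATCG01180. They had 205754 and 205698 counts in control replicate 1, and 395479 and 395279 in CsCl replicate 3. The chloroplast share is therefore not one of messenger RNA alone. Mitochondrial genes took 0.0671 ± 0.00526% in controls and 0.0861 ± 0.0140% with CsCl (n = 3 each, two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). Of the 50 named nuclear genes, 13 share a stretch of 100 bases at 95% identity or more with another gene, so reads from one copy can count towards another: EARLI1 with AZI1, CYP79F1, GSTF7, HSC70-2, HSP101, HSP23.6-MITO, LHCB1.3, PYK10, RBCS1A, RBCS3B, SAG13 and VSP1. Their values are uncertain to that extent.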

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

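Thinned libraries, halved counts, the GC and length correction and CNX2 at its meant locus were chosen after seeing the data; they left the 4 gene counts within 1.5 times and the members called in the lists of small and large heat shock proteins, ER stress, sulfate and glucosinolate likewise. No alternative turned the direction of a named gene past the test. Of the 41 such genes, 24 kept the call under each of the 20 alternatives that tested them and 17 lost it under at least 1. Near 0, RBCS1A moved to 0.0080 with total counts only, and leaving out a library gave HSP101 -0.067 to 0.078 and RCA -0.11 to 0.033.

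With total counts only 180 genes were lower. This fit differs from the main one only in its scaling, and the median log2 fold change of all tested genes was 0.044 against 0.0052. The share of calls thus shifted with a common upward offset. Which scaling is nearer the truth was not tested. No low-count filter gave 301 higher and 518 lower, with more genes tested (26389); the stricter filter gave 50 genes at least 2-fold higher, with fewer genes tested (19176). DESeq2 gave 425 lower, and the cause was not tested. An adjusted p under 0.01 gave 80 higher, 106 lower and 52 at least 2-fold higher, 1 large heat shock protein, 1 ER stress gene and 3 sulfate genes, by its stricter threshold. The test against a fold of 2 gave 20 and 1.

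Leaving out a library, with fewer samples, gave 89 to 231 genes higher, 90 to 330 lower, 53 to 105 at least 2-fold higher and 7 to 13 at least 2-fold lower; 2 to 5 large heat shock proteins, 1 to 2 ER stress genes and 6 to 8 small heat shock proteins higher; and 4 to 12 sulfate and 7 to 10 glucosinolate genes lower. The highest counts for all genes came without control replicate 1 and the lowest without CsCl replicate 3 (89 higher, 133 lower) or 2 (92 higher, 90 lower).

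With an estimated correlation, set test adjusted p became 0.135 for small and 0.660 for large heat shock proteins, 0.299 for sulfate and 0.299 for glucosinolate; fry gave 0.20 for large heat shock proteins and 0.0545 for sulfate. The camera tests put the same question with a different correlation between genes. It was preset at 0.01, against estimates of 0.069 for small and 0.24 for large heat shock proteins, 0.39 for sulfate and 0.45 for glucosinolate. That correlation is not the only difference between the tests. For antioxidant enzymes the estimate of -0.025 lay below the preset value, yet the unadjusted camera p rose from 0.00537 to 0.0380. The lost calls therefore cannot be put down to correlation alone. Fry puts a different question. The replicate numbers showed no pairing of the samples: same-numbered deviations correlated at -0.077, 0.039 and -0.0096, and 1 of 6 samples correlated best with its own number. So few pairs cannot exclude that a number marks a shared plate or day. With the replicate block, 146 genes were higher, 210 lower, 76 at least 2-fold higher and 11 at least 2-fold lower, and 1 ER stress gene was higher. Depth limits the genes with fewer than 10 counts per control library. Among those named by the fixed rule these are HSP23.6-MITO, PR1 and SAG13, whose folds carry wide intervals. Other genes given below, such as NDB4 and AT2G04050, are limited likewise.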

Other observations

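The tests of root tissue share, the term enrichment and the GC, thinning and halving fits were chosen only after the gene results were seen. Annotation terms gave a second view of the called genes. Of 1190 tests, 2 terms passed among higher genes and 15 among lower genes. Response to heat held 7 higher genes against 0.492 expected (adjusted p = 0.000163), among them HSP17.4, HSP17.6A and BIP3. All 7 were already counted as higher in the lists of heat shock proteins and ER stress. Those lists were fixed knowing the series title, so this term is not independent evidence. Defence response to fungus held 6 against 0.509 (adjusted p = 0.00268), among them EARLI1, AZI1 and TI1, of which EARLI1 and AZI1 share near-identical stretches. Among lower genes, heme binding held 16 against 2.99 expected (adjusted p = 6.33e-05), made up of cytochromes P450 such as CYP705A12 and CYP81F4 and of peroxidases such as PER64 and PRXR1. Defence response, the term with the most lower genes, held 17 against 3.76 (adjusted p = 8.95e-05), among them EDS5 and VSP1, so genes with defence terms were found in both directions. Response to biotic stimulus held 6 against 0.268 (adjusted p = 8.95e-05), including the major latex protein genes MLP28, MLP34, MLP43 and MLP329. All 6 are also among the 17 of defence response, so these terms are not separate results. Shared stretches were not searched for these genes, so reads counted at more than 1 copy may link their calls. Lipid transport held 6 against 0.861 (adjusted p = 0.0231), and sulfate transmembrane transport 3 against 0.169 (adjusted p = 0.0413), namely SULTR2;1, SULTR4;1 and SULTR4;2. Beside these lower terms, 4 of 15 root tissue markers were lower, and 1 without CsCl replicate 2 (fry adjusted p = 0.0295; camera adjusted p = 0.299 with an estimated correlation). The terms were not tested against a smaller share of root tissue.

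Of 21 tested genes linked to mitochondrial dysfunction, 13 were higher with CsCl, 1 was lower and the others did not pass the edgeR test. The values of 9 members had been seen before the list was written, and 8 of the 13 higher genes were among those 9. The alternative NADH dehydrogenase gene NDB4 had 4, 0 and 2 counts in controls and 72, 86 and 70 with CsCl, the transporter gene AT2G04050 had 4, 8 and 6 against 262, 388 and 318, and the alternative oxidase gene AOX1A went from 34.0 ± 3.08 to 45.0 ± 3.65 CPM (n = 3); these had been seen before the list was written, so a hypothesis of a mitochondrial dysfunction response was tested on 12 members not yet looked at. Of these, 91.7% (11 of 12) had higher values and 5 passed the edgeR test, among them HRG1, CYP81D8 and SOT12. The fry test of limma on these members gave an adjusted p = 0.00068 (over this list and the copper list). The result is consistent with that hypothesis, which rests on transcripts alone. It does not single out mitochondria, since such genes also respond to other stresses, and AATP1, listed as rising, fell from 2.53 ± 0.163 to 0.912 ± 0.202 CPM. Shared stretches were not searched for the 12 members. Reads counted at more than 1 copy may therefore link them to members already seen.

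Copper-responsive genes gave a mixed picture. FRO5 fell from 5.15 ± 1.56 to 0.877 ± 0.263 CPM and FRO4 from 42.0 ± 9.05 to 25.3 ± 2.21, both ferric or cupric reductase genes of copper uptake, while the copper/zinc superoxide dismutase gene CSD1 rose from 22.0 ± 3.34 to 51.0 ± 4.29. These 3, with CSD2, AT1G71200 and the iron superoxide dismutase gene FSD1, were seen before the hypothesis of a shift towards the copper-sufficient pattern was written. FSD1 did not pass the test (log2 fold change -0.18, edgeR adjusted p = 0.214). Of 14 tested members not yet looked at, 64.3% (9) moved in the listed direction, below the 75% set beforehand, with a signed fry adjusted p of 0.0266; 5 passed, namely COPT2, ZIP2 and YSL2 lower and CCS and COX5B-1 higher, and the laccases LAC3, LAC12, LAC13 and LAC17 had values below 0. Over all 20 tested members, the 6 seen beforehand included, the signed median was 0.32, and 0.33 after correction for GC content and length, with 10 members past the test in the listed direction before and 10 after. This argues against such a trend as the whole cause for the members that passed. Over the 14 others the signed median was 0.067, and 0.086 after correction, which decides nothing, and the hypothesis itself stays open because 5 of the 14 went the other way. Shared stretches were not searched for these 14 or for FRO4 and FRO5, so reads counted at more than 1 copy may link their values.

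The fall of glucosinolate and sulfate transcripts was weighed against sequencing and tissue effects. After correction for GC content and length the medians were -0.42 and -0.39, so such a trend does not account for them. With all libraries thinned to the smallest total 9 and 10 members were lower, so these calls do not rest on the depth of CsCl replicate 3. A smaller share of root tissue was weighed by the mean of the 15 root markers, a log2 change of -0.16. The glucosinolate list fell by 2.56 SD between libraries more than that mean, and the sulfate list by 1.17 SD more. Single markers ranged from -0.47 to 0.33, with 3 above 0. CASP2 at -0.47 and PYK10 at -0.38 lay near the glucosinolate median. The mean is therefore no bound on what a smaller root share would do, and the test decides for neither list. A response to CsCl itself remains a hypothesis for both lists, and a smaller root share may contribute to either.

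For the small heat shock proteins, 6 of the 7 members that rose have no other gene with a near-identical stretch, which argues against reads shared between paralogs. With counts halved, as if each pair were counted once, 7 members were higher, and with thinned libraries also 7. The calls therefore do not rest on counted mates or on the depth of CsCl replicate 3. Neither step is made to alter the ratio between the groups, so neither tests a cause of the rise. A response to CsCl may be involved, as a hypothesis found and tested on the same data.

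Of the 10 ways to split the 6 samples into 3 and 3, only 1, the real one, reached each of the 4 gene counts (edgeR): 177 higher, 277 lower, 81 at least 2-fold higher and 13 at least 2-fold lower, against a highest value of 0 in any other split. With 10 splits the share cannot fall under 0.05.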
